A study of Drosophila melanogaster with 6 samples.

How the data were processed

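Gene expression was measured in 6 samples of Drosophila S2 cells, 3 treated with dsRNA against GFP and 3 with dsRNA against spotted-dick, each hybridised to an Affymetrix Drosophila_2 array, per the file headers. The deposited values were 1 intensity per probe set and array on a linear scale, a signal that combines the several probes of a transcript. The software that combined the probes, its background correction and any scaling of the arrays are not given in the sources used here, and no detection calls were used here. The deposited intensity table had 18894 probe sets, of which 125 were Affymetrix controls and 18769 measured fly transcripts. Groups and replicate numbers were taken from the sample titles.

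Of the 18769 probe sets, 13647 were paired with 1 gene by the platform annotation, 402 with several genes and 4720 were unnamed here. Gene IDs of 13544 probe sets matched the RefSeq gene table of the Release 6 assembly, which was used for names and for which genes neighbour each other. The genome build behind the array is not stated, so no coordinates were used. Probe sets with several genes were tested but not named. Where a gene had several tested probe sets, the probe set with the highest mean over the 6 arrays stood for it.

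The fitted values were log2(signal + 16), so a fold change understates the change of a dim probe set. The design asked for values as deposited if the highest and lowest array medians lay within 1.5 times of each other. That ratio was 1.28, so no further normalization was applied, although the trimmed mean signal (2% trimmed from each end) differed 1.51 times between the brightest and the dimmest array. The medians, 12.4 to 15.9, all lay under 17.4, the 95th percentile of foreign-sequence control probe sets, so their ratio is a weak measure of brightness. Probe sets with a mean below the 40th percentile were left out, which left 11261. Spotted-dick RNAi was compared with GFP RNAi by limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend), and a probe set was called at a Benjamini-Hochberg adjusted p under 0.05. In that fit limma estimated no difference between probe sets in their spread beyond the trend, so the spread was treated as known and very small p-values rest on that assumption. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

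The 25 gene lists, the rule for the genes named, the tests of genes and lists and most alternatives were fixed before the data were examined. Of 661 list members, 656 were matched to 1 gene and 491 of these had a probe set of their own. Lists with at least 4 tested genes were tested with limma's camera (preset correlation 0.01, two-sided, Benjamini-Hochberg over lists), with camera using an estimated correlation and with fry. The genes named were pita and Orc4, the 12 largest rises and 12 largest falls among called genes whose groups did not overlap (all 10 rises, since fewer passed), all tested members of the origin licensing and firing list, and of each other list up to 4 members with the smallest p. A list's shift is the mean log2 fold change of its members minus the mean over all tested genes.

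The arrays were washed on 2 fluidics stations, per the file headers. Station 1 held GFP replicates 1 and 2 and spotted-dick replicate 1, and station 2 held GFP replicate 3 and spotted-dick replicates 2 and 3. Each change given within a station therefore rests on 1 array of 1 group. All 6 arrays were scanned on 1 day, the 3 GFP arrays before the 3 spotted-dick arrays, so scan order and group cannot be told apart. Alternatives were quantile normalization, median centring, pseudocounts of 1 and 64, no filter, a filter at the 60th percentile, limma without the trend or with robust estimation, the replicate number or the station as a block, leaving out each array, and the mean of a gene's probe sets. Scaling to the 9 hybridisation control probe sets, which measure transcripts added to the hybridisation mix, and quantile normalization together with either block were chosen after seeing the data. Background was judged by 100 control probe sets for foreign or synthetic sequences, with a median signal of 4.5 and a 95th percentile of 17.4.

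The fit was tested on simulated data for this comparison: 18769 probe sets in 10 draws, with 200 changed in each and the measured brightness of each array. As deposited, 78.7% of probe sets changed by 1 on the log2 scale and 94.3% of those changed by 2 were called, and 23.2% of all calls were of unchanged probe sets. After quantile normalization these values were 81.9%, 92.2% and 5.33%, and with equally bright arrays and no normalization 5.13% of calls were of unchanged probe sets. In a simulation of the set test, 4.52% of 199 unshifted lists of 25 genes had p under 0.05. Its probe sets varied independently and its arrays were equally bright. As deposited, the estimated correlation within most lists lay far above the preset 0.01, at 0.75 for origin licensing and firing and 0.94 for proteasome genes. The simulation therefore does not give the rate of false list calls in these data.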

Results

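The series profiled gene expression in Drosophila S2 cells, an embryonic cell line with hemocyte-like features, 5 days after treatment with double-stranded RNA (dsRNA). Such RNA is taken up by these cells and leads to degradation of the matching mRNA (RNA interference, RNAi). In 3 samples the dsRNA matched spotted-dick, the gene now named pita (CG3941), which encodes a zinc-finger DNA-binding protein. In the other 3 it matched GFP, a jellyfish protein with no fly counterpart, as a control. The comparison asks which transcripts change when spotted-dick is depleted, and, from what is known of the study, whether Orc4 is among them. The sample labels name no other dsRNA against spotted-dick and no rescue of the gene. Effects of its loss and other effects of the dsRNA therefore cannot be told apart. Values are deposited array signals (linear intensity). The trimmed mean signal was 189.6, 160.1 and 125.8 in GFP replicates 1 to 3 and 125.4, 138.8 and 126.6 in spotted-dick replicates 1 to 3. The number of arrays limits the precision. Since the labels do not say that replicates came from separate cultures, p-values measure at most the spread between these samples. As deposited, the fit took that spread from the trend over all tested probe sets. Its standard errors and p-values therefore do not reflect a probe set's own spread, and very small p-values should not be read at face value.

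The targeted transcript was depleted in every spotted-dick array. The pita signal was 335.9, 333.2 and 269.7 in the GFP arrays and 25.9, 46.6 and 28.7 in the spotted-dick arrays. On the log2(signal + 16) scale pita fell by 2.74 ± 0.22 (SE, n = 3 and 3, limma adjusted p = 1.68e-33), a change of -2.54 relative to the median of all tested probe sets, which itself lay at -0.20. Orc4 (CG2917), a subunit of the origin recognition complex that marks DNA replication origins, had signals of 141.1, 146.0 and 100.9 in the GFP arrays. In the spotted-dick arrays its signals of 2.7, 14.2 and 4.0 lay below the 95th percentile of the foreign-sequence controls, 17.4. Orc4 fell by 2.68 ± 0.22 (SE, limma adjusted p = 1.04e-30), or -2.48 relative to the median. After quantile normalization the limma adjusted p-values were 6.96e-08 for pita and 1.58e-06 for Orc4. Both genes passed in all 19 refits run at the level of probe sets. Within station 1 and station 2 the changes were -3.06 and -2.43 for pita and -3.09 and -2.25 for Orc4. Dcp-1, a caspase gene that neighbours pita, had a change of -0.58 that did not pass the test (limma adjusted p = 0.257).

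Several transcripts fell further than the target itself. The largest fall was that of CG15715, from a signal of 1553 ± 345 to 17.0 ± 3.6 (SD, n = 3), a log2 change of -5.55 ± 0.22 (SE, limma adjusted p = 1.26e-130, or 3.45e-14 after quantile normalization). Its mean in the spotted-dick arrays lay under 17.4, the 95th percentile of the foreign-sequence controls, as did those of Orc4, Atox1 and scaf, so the sizes of these falls depend on the pseudocount. For CG15715 the change was -6.43 with a pseudocount of 1 and -4.30 with 64, for Atox1 -4.76 and -2.68, for Orc4 -4.30 and -1.44, and for scaf -3.13 and -1.32. Nazo fell from 915.4 ± 219.8 to 32.3 ± 5.3 (log2 change -4.25). Atox1, a copper chaperone, fell from 452.9 ± 111.9 to 15.4 ± 0.6 (log2 change -3.87), below the foreign-sequence 95th percentile in all 3 spotted-dick arrays. Falls also passed for CG33462 (log2 change -3.59), TfIIEalpha, which encodes a subunit of the general transcription factor TFIIE (-3.13), CG18528 (-2.91), CG7824 (-2.50) and scaf, a serine protease homologue (-2.28). The mitochondrial ribosomal protein gene mRpL1 fell by 2.22. MtnA, a metal-binding metallothionein and among the brightest probe sets, fell from 12698 ± 1093 to 3028 ± 316 (log2 change -2.06). These 12 largest falls, pita and Orc4 included, passed in all 19 refits.

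**Figure D1:**
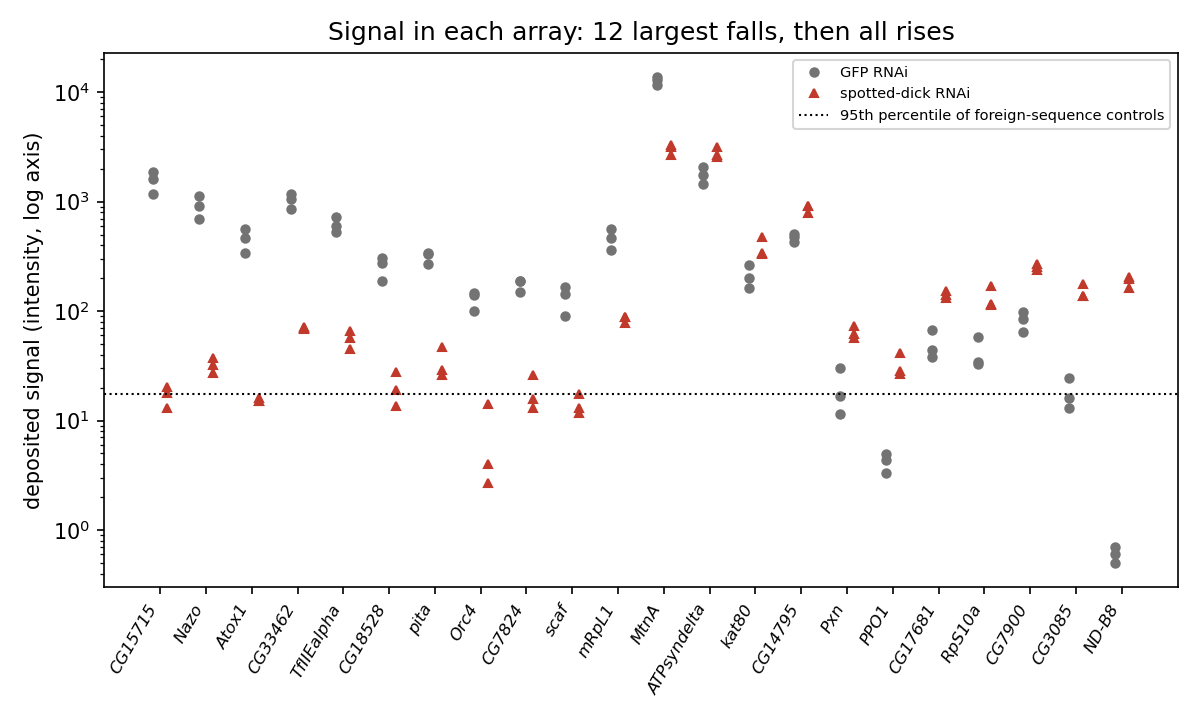
Deposited signal (log axis) in each of the 3 GFP RNAi arrays (circles) and 3 spotted-dick RNAi arrays (triangles) for the 12 genes with the largest falls and all 10 genes that rose, with the 95th percentile of foreign-sequence controls (17.4) as a dotted line. Only called genes whose groups do not overlap were eligible to be shown. ND-B8 lies at 0.5 to 0.7 in the GFP arrays and at 163.8 to 206.7 in the spotted-dick arrays.

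Fewer transcripts rose. ND-B8, a subunit gene of mitochondrial complex I, had signals of 0.6, 0.5 and 0.7 in the GFP arrays, far under the foreign-sequence 95th percentile of 17.4, and of 196.9, 206.7 and 163.8 in the spotted-dick arrays. Its log2 change was 3.62 ± 0.22 (SE, limma adjusted p = 4.69e-57, or 2.24e-10 after quantile normalization), and it was 6.89 and 1.97 with pseudocounts of 1 and 64. CG3085 rose from 17.8 ± 5.9 to 149.5 ± 22.5 (log2 change 2.30), CG7900 by 1.46, CG17681 by 1.28 and RpS10a, a paralogue of a ribosomal protein gene, by 1.37. Transcripts of PPO1, a prophenoloxidase of the melanization pathway, rose from 4.2 ± 0.8 to 32.0 ± 7.8 (log2 change 1.24), and those of Pxn, an extracellular matrix peroxidase, rose by 1.20. CG14795 rose by 0.86, kat80, a katanin microtubule-severing subunit, by 0.81 and ATPsyndelta, an ATP synthase subunit, by 0.68. ND-B8, CG3085, CG7900 and CG17681 passed in all 19 refits. The call for ATPsyndelta ended with the station as a block (adjusted p = 0.0536; range over refits 1.45e-08 to 0.460), with changes of 0.42 and 1.01 within station 1 and station 2. Leaving out GFP replicate 2 or any spotted-dick replicate ended the calls for CG14795 (highest adjusted p = 0.358), kat80 (0.541) and ATPsyndelta (0.460), and leaving out spotted-dick replicate 2 ended that for PPO1 (0.0547). Without the filter on dim probe sets the calls for RpS10a (adjusted p = 0.0538), PPO1 (0.0931) and Pxn (0.230) ended as well, each the highest of their refits.

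In all, 140 of 11261 tested probe sets passed, 11 higher and 129 lower in the spotted-dick arrays. Of these, 53 changed at least 2-fold, 7 higher and 46 lower, against 9 higher and 29 lower after quantile normalization and 13 higher and 25 lower after scaling to the hybridisation controls. After quantile normalization 110 of the 140 were still called. In the simulation with these arrays' brightness, 23.2% of calls as deposited were of unchanged probe sets. Passing as deposited therefore may not hold the nominal 0.05. At the level of genes, 117 of 8273 passed, 10 higher and 107 lower, and in 113 of them the groups did not overlap. Groups did not overlap for 14.0% of tested probe sets, against 10% by chance. GFP replicates 1 and 2 were the brightest arrays by trimmed mean. The median log2 level of the tested probe sets per array differed between groups by -0.42 in station 1 and 0.05 in station 2. This level is not the median signal over all probe sets. The balance of directions moved with scaling. Quantile normalization gave 229 probe sets, 68 higher and 161 lower, and scaling to the hybridisation controls, themselves lower by 0.28 in the spotted-dick arrays, gave 70 higher and 123 lower. Counted whether or not the groups overlapped, 10 genes rose and 86 fell as deposited and also after quantile normalization, and none called in both settings changed direction. Without the filter on dim probe sets 28 passed. With 1 array left out the count ranged from 53 without spotted-dick replicate 3 to 3716 without GFP replicate 3. Without GFP replicates 1 and 2 it was 88 and 54, without spotted-dick replicates 1 and 2 it was 62 and 75, and with the station as a block it was 92.

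**Figure D2:**
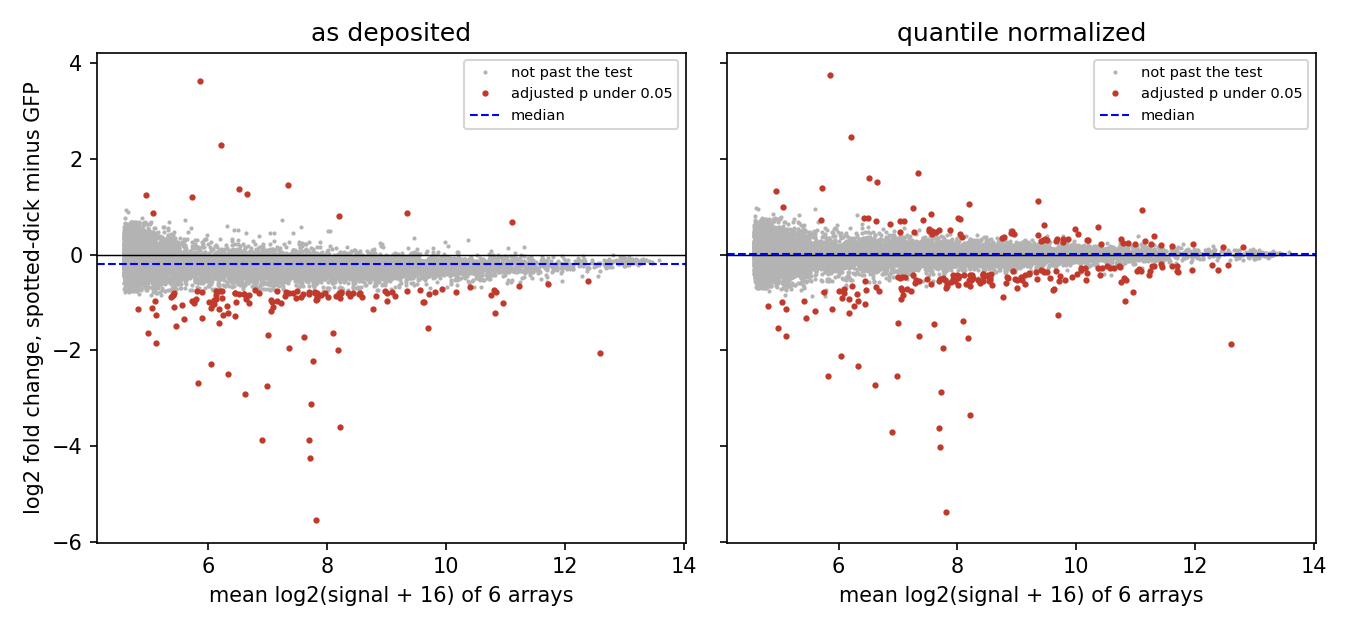
Log2 fold change (spotted-dick RNAi minus GFP RNAi) against the mean log2(signal + 16) of 6 arrays for the 11261 tested probe sets, as deposited (left) and after quantile normalization (right), with called probe sets in red and the median as a dashed line. The median lies at -0.20 as deposited and at 0.01 after quantile normalization, and 140 and 229 probe sets are called.

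Among the genes that license and fire replication origins, Orc4 alone passed the test, over all genes and adjusted over the list alone, as it did after quantile normalization and without any single array other than GFP replicate 3. Without GFP replicate 3, the dimmest of the GFP arrays, the median change of all tested probe sets was -0.33. In that refit 3680 of all 11261 tested probe sets passed as lower, and so did 8 of the 20 members, Orc4 included. The other 19 of 20 tested members had changes from -0.44 for Mcm3, a subunit of the MCM helicase, to 0.08 for Cdc6, an origin loading factor, or from -0.24 to 0.29 relative to the median of all tested probe sets. After Orc4, the smallest p-values belonged to Mcm3 (-0.44 ± 0.22, SE, limma adjusted p = 0.472), the kinase gene Cdc7 (-0.33 ± 0.22, adjusted p = 0.549) and its activator chif (-0.32 ± 0.23, adjusted p = 0.559). Sld5 followed at -0.30 ± 0.22 (adjusted p = 0.564) and mus101 at -0.28 ± 0.22 (adjusted p = 0.572). The remaining tested members were dpa, Orc2, Psf3, Orc1, Cdc45, dup, Mcm6, Mcm5, Psf1, Orc5, Mcm10, Psf2, Mcm2 and Cdc6. Orc6, Mcm7, geminin and lat were also on the list but were not tested, lat because its name was not matched to 1 gene. Nothing can be said of these from this comparison. The list as a whole did not pass (shift -0.13, camera adjusted p = 0.158; 0.968 with an estimated correlation; median shift -0.04 in station 1 and 0.11 in station 2). Orc4 carried most of that shift, which was -0.01 over the other 19 members. Its direction depended on scaling: after quantile normalization the mean lay at -0.08 and the median at 0.00 relative to all genes while camera gave an upward direction (adjusted p = 0.917).

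**Figure D3:**
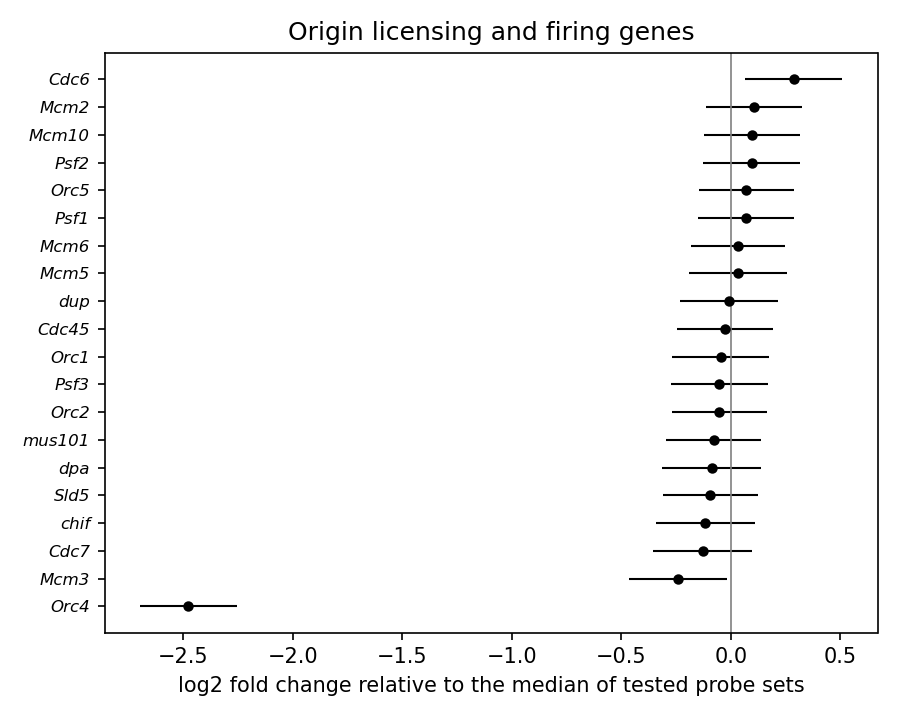
Log2 fold change relative to the median of all tested probe sets (spotted-dick RNAi minus GFP RNAi, points; bars, SE) for the 20 tested origin licensing and firing genes. Orc4 lies at -2.48 and the other 19 genes lie between -0.24 and 0.29.

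No member of the other cell-cycle lists passed in limma as deposited. This covered 25 tested replication fork genes, 12 G1/S regulators, 27 mitosis genes, 13 condensin and cohesin genes and 17 DNA damage response genes, and adjusted over each list alone the counts were also 0. Over all genes, 1182 probe sets had an unadjusted p under 0.05. Their camera adjusted p-values were 0.879, 0.917, 0.682, 0.827 and 0.928 in that order. Without GFP replicate 3, 3716 of all 11261 tested probe sets passed, 3680 of them as lower. In that refit 11 replication fork, 4 G1/S, 7 mitosis, 6 condensin and cohesin and 8 DNA damage response genes passed as lower. Without each of the other arrays none of these lists' genes did. After quantile normalization 1 mitosis gene passed, fzr, an activator of the anaphase-promoting complex (0.48, adjusted p = 0.0245, chosen after its value was seen). The mitosis list then passed as higher (shift 0.11, camera adjusted p = 0.0053; 0.664 with an estimated correlation), as it did with median centring (shift 0.05, camera adjusted p = 0.0432; 0.697 with an estimated correlation) and with scaling to the hybridisation controls (0.0250; 0.950).

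Genes of energy metabolism and translation mostly did not pass, with a few large exceptions. Of 67 oxidative phosphorylation genes 2 rose, ND-B8 and ATPsyndelta, and none fell, with the same count adjusted over the list alone. As deposited the list did not pass (shift 0.10, camera adjusted p = 0.158; shift 0.05 without ND-B8). It passed as higher after quantile normalization (shift 0.12, camera adjusted p = 0.00051), with median centring (0.00295), with scaling to the hybridisation controls (9.09e-05), with the filter at the 60th percentile (0.020) and without GFP replicate 1 (0.00890), and with an estimated correlation in none of these (adjusted p = 0.542, 0.697, 0.765, 0.994 and 0.996). Of 71 mitochondrial ribosomal protein genes mRpL1 fell and the other 70 did not pass, mRpL24 having a change of -0.68 (limma adjusted p = 0.124). After quantile normalization mRpL24 also passed as lower (-0.42), and tko (0.43), mRpS22 (0.32) and the ATP synthase gene ATPsynC (0.19), chosen after their values were seen, passed as higher. Of 33 cytoplasmic ribosomal protein genes RpS10a rose and the other 32 did not pass. In this list 32 of 33 members lay above the median of all genes as deposited (median change -0.13 against -0.21). The list median relative to all genes was 0.14 in station 1, -0.01 in station 2 and 0.01 after quantile normalization. The list passed as higher with median centring (shift 0.12, camera adjusted p = 2.59e-06; adjusted p = 0.697 with an estimated correlation) and with scaling to the hybridisation controls (camera adjusted p = 3.80e-09; adjusted p = 0.887 with an estimated correlation), and not after quantile normalization (camera adjusted p = 0.153). Of 9 glycolysis genes Tpi, triose phosphate isomerase, fell from 2855 ± 592 to 1383 ± 109 (log2 change -1.02 ± 0.19, SE, limma adjusted p = 1.62e-05) and passed in all 19 refits, while Hex-A (-0.50) and Gapdh1 (-0.37) did not pass. Adjusted over the list alone the counts for these 3 lists were the same. Their camera adjusted p-values were 0.562, 0.602 and 0.158, and none of 26 proteasome genes passed (0.827). Without GFP replicate 3, 3680 of all 11261 tested probe sets passed as lower. Among list members these were 28 of 66 oxidative phosphorylation, 33 of 71 mitochondrial ribosomal, 7 of 33 cytoplasmic ribosomal, 7 of 9 glycolysis and 16 of 26 proteasome genes. The mitochondrial ribosomal and glycolysis lists also passed as lower in that refit (camera adjusted p = 0.0320 for both; adjusted p = 0.991 with an estimated correlation).

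Of 15 humoral immunity genes 3 fell and none rose, and adjusted over the list alone 4 fell. The antimicrobial peptide genes DptB and AttD fell by 1.00 and 0.92 (limma adjusted p = 0.000728 and 0.00325; the groups overlapped for DptB), and PGRP-LB, a peptidoglycan-degrading enzyme gene, by 0.75 (adjusted p = 0.0439). PGRP-SB1 had a change of -0.58 (adjusted p = 0.249). After quantile normalization DptB and AttD passed and PGRP-LB did not (-0.52, adjusted p = 0.162; range over refits 5.66e-04 to 0.631). The list passed (shift -0.21, camera adjusted p = 0.0325), but not with an estimated correlation (adjusted p = 0.968), nor with the station as a block (shift -0.19, adjusted p = 0.0667). Its median shift was -0.13 in station 1 and -0.11 in station 2. The called genes differed more between station 1 and station 2, with changes of -1.50 and -0.40 for DptB and -1.45 and -0.35 for AttD. Those of PGRP-LB were -0.89 and -0.58. These values rest on spotted-dick replicate 1 alone in station 1 and on GFP replicate 3 alone in station 2. The array medians differed by -0.42 and 0.05 within the stations, so a station difference of these genes cannot be told from single arrays and brightness. Leaving out GFP replicate 1 or spotted-dick replicate 1 or 3 also ended the call of the list (adjusted p = 0.105, 0.138 and 0.0919). For DptB and AttD, leaving out GFP replicate 2 (adjusted p = 0.146 and 0.162) or spotted-dick replicate 1 (0.204 and 0.323) ended the calls, and for DptB also spotted-dick replicate 3 (0.290). The call for PGRP-LB was kept only when GFP replicate 3 was the array left out. Then 10 members of the list passed as lower, as did 3680 of all 11261 tested probe sets.

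Among markers of blood cell types, 1 crystal cell and 1 plasmatocyte marker rose. Of 4 crystal cell markers PPO1 rose, while PPO2 (0.47), lz (0.05) and klu (-0.01) did not pass. This list passed (shift 0.64, or 0.37 without PPO1; camera adjusted p = 0.00023), but not with an estimated correlation (adjusted p = 0.899), and its median shift was 0.53 in station 1 and 0.70 in station 2. It rests on signals near background: 3 of the 4 mean signals in the GFP arrays, those of PPO1, PPO2 and lz, lay at or under 17.4, and lz stayed there in the spotted-dick arrays. The values of lz and klu near 0 lie above the median of all genes, -0.21, without a rise. Of 15 plasmatocyte markers Pxn rose and the others did not pass, crq and eater having changes of -0.57 and -0.40 (camera adjusted p = 0.827). No lamellocyte marker of 8 passed over all genes, and mys (-0.57) and msn (-0.62) passed as lower adjusted over the list alone and, over all genes, after quantile normalization. The lamellocyte list did not pass as deposited (shift -0.17, camera adjusted p = 0.158) and passed as lower after quantile normalization (adjusted p = 0.0374; 0.542 with an estimated correlation), with median centring (0.0125; 0.517) and without GFP replicate 3 (0.0320; 0.991). None of 4 fat body, 5 neuron or 7 ovary markers passed (camera adjusted p = 0.387, 0.835 and 0.449), but 3, 3 and 6 of them had mean signals at or under 17.4, the 95th percentile of the foreign-sequence controls, in both groups, so these tests ran mostly on transcripts not seen above background. After quantile normalization the fat body marker Apoltp was higher (0.76, adjusted p = 0.000794; range over refits 0.000243 to 0.867). As deposited, the neuron marker elav passed as lower adjusted over the list alone (-0.59), and it did not pass over all genes after quantile normalization (-0.34). A single muscle marker, Act88F, was tested, with mean signals under that level in both groups, and did not pass (0.00). Without GFP replicate 3, 8 plasmatocyte and 7 lamellocyte markers and 1 neuron marker passed as lower, and Apoltp as higher. Of all 11261 tested probe sets, 3680 passed as lower and 36 as higher in that refit.

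The stress and regulatory lists held a single gene past the test. In the ecdysone response list ftz-f1, a nuclear receptor gene, fell by 0.77 (limma adjusted p = 0.0385) and the other 12 of 13 members did not pass (camera adjusted p = 0.879). The ftz-f1 call ended after quantile normalization (-0.51, adjusted p = 0.205; range over refits 8.80e-05 to 0.552) and without any single array other than GFP replicate 3. No gene of the lists for apoptosis (7 tested), insulator and architectural proteins (14), heat shock (7), the unfolded protein response (15) or small RNA pathways (12) passed over all genes. Adjusted over the list alone, the apoptosis genes Dcp-1 and egr, a tumour necrosis factor homologue, passed as lower (-0.58 and -0.50), and egr passed over all genes after quantile normalization (-0.24, adjusted p = 0.0388; range over refits 0.000236 to 0.867). The camera adjusted p-values of these 5 lists were 0.449, 0.736, 0.928, 0.602 and 0.602. Among the members with the smallest p were ZIPIC (-0.37), E(bx) (-0.36), Hsp26 (-0.50), Manf (-0.32) and aub (-0.50), none past the test. Without GFP replicate 3, 5 apoptosis, 8 insulator, 3 heat shock, 11 unfolded protein response, 5 small RNA and 7 ecdysone response genes passed as lower. So did 3680 of all 11261 tested probe sets.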

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

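Hybridisation control scaling and quantile normalization with a block were chosen after the data were seen. Under the alternatives run, no probe set called as deposited was called in the opposite direction. Of 128 named genes 27 passed, 17 of them under every alternative and 10 not under at least 1. Of the other 101, 70 passed under at least 1 alternative, many of them under 1 only. The fit without GFP replicate 3 called 3716 probe sets, at a median change of -0.33 over all tested probe sets. In addition, 145 changes of sign concerned gene values that passed on neither side and 69 such changes concerned lists. The total of 140 became 229 after quantile normalization, 28 without a filter, 93 with the replicate block, 92 with the station block and 53 to 3716 when an array was left out. Higher probe sets (11) became 68 after quantile normalization, 52 with median centring, 4 without a filter, 7 with the replicate block and 6 to 36 when an array was left out. With the added settings they became 70 (hybridisation control scaling), 58 (quantile normalization and station block) and 53 (quantile normalization and replicate block). Lower probe sets (129) became 24 without a filter, 78 with the station block and 46 to 3680 when an array was left out. Those changed at least 2-fold (53) became 81 and 24 with pseudocounts of 1 and 64, 28 without a filter and 43 to 99 when an array was left out. The humoral immunity list (-0.21) did not pass with the filter at the 60th percentile (-0.17), without the trend (-0.21), with the station block (-0.19; -0.16 after quantile normalization), with an estimated correlation (-0.21) or in fry (mean change -0.41), and its range when an array was left out was -0.25 to -0.16. The crystal cell list did not pass with an estimated correlation (0.64) or in fry (mean change 0.44), and too few members were left for a test with the filter at the 60th percentile. For the origin licensing and firing list the direction of camera was upward after quantile normalization (mean shift -0.0804), also with the station block (-0.0750) or the replicate block (-0.0804), and it passed in none of these. Without the filter more probe sets were tested and the estimated spread differed, and for the other changes the cause was not tested. The replicate numbers did not pair the samples: deviations of same-numbered arrays correlated at -0.17, -0.01 and 0.07 as deposited, where no array correlated best with the array of its own number, and at -0.06, -0.03 and 0.05 after quantile normalization, where replicate 3 did. Signals near 17.4, the 95th percentile of foreign-sequence controls, limit what can be said of dim genes such as PPO1 and ND-B8 in GFP arrays, of the fat body, neuron, muscle, ovary and crystal cell markers, and of 7 of the 67 oxidative phosphorylation and 4 of the 13 ecdysone response genes tested, which lay at or under it in both groups.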

Other observations

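The tests of splits by total count and by number of lists, and that of other metallothionein genes, were set before their results were seen, and the other tests below were chosen after. Beyond the named genes, and chosen after their values were seen, transcripts that fell at least 2-fold included ringer (log2 change -1.69), c11.1 (-1.64), nemy (-1.52), the tissue inhibitor of metalloproteases Timp (-1.14), the lipid droplet gene Jabba (-1.21) and APC7 (-1.02), a subunit gene of the anaphase-promoting complex. Each passed after quantile normalization too, with changes of -1.43, -1.39, -1.26, -0.93, -0.97 and -0.79.

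Other splits of the 6 arrays into 3 and 3 were too few, 10 with the real one, for a share under 0.05. As deposited, 2 splits gave at least the real 140 probe sets. The other, which set GFP replicates 1 and 2 and spotted-dick replicate 2, the brightest arrays, against the rest, gave 636, which points to brightness as a structure of the samples. After quantile normalization the real split gave 229 and the highest other split 1, so 1 of 10 splits reached the real count. For changes of at least 2-fold, 1 of 10 splits reached the real 53, and the highest other gave 20. For lists called, 5 of 10 splits reached the real 2, and the highest other gave 5.

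As deposited the median change was -0.20, with GFP replicates 1 and 2 the brightest arrays and GFP replicate 3 within the range of the spotted-dick arrays by trimmed mean, and far more probe sets were called lower than higher. Over the 6 arrays the median log2 level of the tested probe sets followed the hybridisation controls, which do not come from the cells. Pearson r was 0.981 (exact permutation p = 0.00694) and Spearman rho was 0.829 (exact permutation p = 0.0583), with 1 relation computed. Without the 2 arrays farthest from the median, r was 0.826. The controls differed between groups by -0.49 within station 1 and 0.02 within station 2. The median log2 levels differed by -0.42 and 0.05. This relation and these differences fit array brightness behind the median change. A fall of most transcripts stays open. The median change after scaling to the controls was 0.0754, and the controls' change had a standard error of 0.16. Brightness as the whole cause of the excess of lower calls is argued against by 70.3% lower calls after quantile normalization and 74.1% after median centring. Both take the typical transcript as unchanged. After scaling to the controls 63.7% of calls were lower (95% exact binomial interval 56.5 to 70.5, treating probe sets as independent). That interval leaves out the error of the scaling itself, so this share alone does not decide the question. Loss of the DNA-binding protein at activated genes stays open as a biological explanation and was not tested, and scan order cannot be told apart from group.

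Called genes lay next to each other along the chromosomes. In the Release 6 gene order 5 pairs of neighbouring genes were both called as deposited, all falling: CG31778 with CG31777, CG9331 with CG31673, ETH with Orc4, CG18081 with CG15715, and MtnA with CG8500, of which all but Orc4, CG15715 and MtnA were chosen after their values were seen. Random placement of as many calls among the tested genes gave 1.11 pairs on average and 0 to 4 in 95% of 10000 draws (one-sided permutation p = 0.006), and after quantile normalization there were 14 pairs against 3.35 (0 to 7; p = 1e-04, the smallest these draws can give), 12 of them changing the same way, which argues against chance placement. Neighbouring paralogues, shared regulatory DNA, overlapping transcripts or transcription running from gene to gene may each contribute and were not separated.

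ND-B8 was the only probe set at or under 17.4 in all GFP arrays and at or over 100 in all spotted-dick arrays, while those of Atox1 and Orc4 went the other way. A candidate explanation is a neighbouring gene that rose and whose transcript ran on into ND-B8. Relative to the median, its neighbours Secp43 and Gs1l changed by -0.25 (95% interval -0.67 to 0.18) and 0.09 (-0.35 to 0.53), so neither passed, but the highest bound, 0.527, leaves room for a rise and the explanation stays open. The form of this test was changed after these values were seen, from a count of neighbours past the threshold to a bound on their rise, which was then lowered to 0. The GFP signals of 0.5 to 0.7 lay under even the foreign-sequence control median of 4.5. Whether the transcript was absent in GFP arrays or not measured there by this probe set cannot be told. Loss of repression of ND-B8 after spotted-dick depletion stays open and was not tested.

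MtnA and Atox1 both serve metal handling and both fell, which may reflect a lower metal response. Of 16 metal handling genes, listed after the falls were seen, 7 probe sets were tested and the other 5 did not pass as deposited. Of these, ZnT63C had the largest change (-0.52, limma adjusted p = 0.365) and ZnT35C lay at 0.01. The others were the copper transporter genes Ctr1A (-0.16) and ATP7 (-0.34) and the metal-responsive transcription factor gene MTF-1 (-0.28). The test asked whether other metallothionein genes fell, and 0 passed, but none of MtnB, MtnC and MtnD was bright enough to be tested as deposited, so it decides nothing. MtnD had mean signals of 2.0 and 16.6, both under 17.4. Its spotted-dick signals were 8.3, 35.9 and 5.6, so replicate 2 carried the mean. Its change was 0.74 (0.95 relative to the median of tested probe sets), the opposite direction, and it passed in none of the 5 alternatives that tested it.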
